A study of Rattus norvegicus with 9 samples.

How the data were processed

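RNA was sequenced from the synovium, the lining tissue of the joint, of Lewis rats, and 9 libraries fall into 3 groups of 3. The labels give the groups only as NC, AIA and TZG and do not spell these out. From the series title, which names a liquid extract and rheumatoid arthritis, NC was read as the control, AIA as the arthritis model and TZG as the extract group. The labels do not say whether TZG animals had arthritis, nor the dose or timing. Per the labels' protocols, RNA was extracted with RNeasy columns and libraries were made with a SMARTER mRNA-Seq kit. Whether the libraries of a group came from separate animals is not stated in the labels, so p-values measure only the spread between these libraries, which may be technical.

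The authors deposited whole-number read counts per gene for 9 libraries, without normalisation, per the file headers. They also deposited FPKM values, which the file shows to be each count divided by a fixed gene length and by the library total. Their table further holds the authors' mean FPKM per group and their own log2 fold changes, p-values and q-values for the 3 comparisons. Per the submitters' processing notes, fastp, HISAT2, StringTie 1.3.3b and edgeR 3.30.3 were used, with no roles given. The genome build and annotation are not given in the sources used here, and coordinates are printed as the deposited table gives them. The 2 deposited tables are identical, and 1 was used.

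Column names of the table carry a letter and a number. C56, C59, C61, G30 and M6 have numbers that are sample titles in the matching group. The numbers of the other 4 columns, G31, G48, M2 and M8, are in no sample title of their group. These columns were placed by letter, G with TZG and M with AIA. The authors' mean FPKM per group matched the mean of the 3 columns sharing a letter, with a largest relative difference of 7.3e-04. The authors thus grouped the columns in the same way, but it is not known which sample each of the 4 is. A fit with only the 5 columns matched by number was run as an alternative, which leaves M6 alone in AIA and G30 alone in TZG. The 4 FPKM columns of the libraries placed by letter were not used; for the alternative on FPKM, values were recomputed from counts and from gene lengths recovered from the other 5 columns.

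Library totals ran from 12536231 to 16402126 reads. At this depth 3 reads, the limit that a count of 0 allows, correspond to 0.183 to 0.239 CPM in one library, and such limits cover counting error only. No pair of libraries agreed within sampling noise, since the chi-square of their counts was at least 21.4 per gene in every pair, so each was kept as 1 replicate. Pearson correlations of log2 CPM across genes were 0.933 to 0.981 within groups and 0.815 to 0.976 between groups; genes are not independent replicates.

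The main test was edgeR 4.0.16 (R 4.3.3) with its robust quasi-likelihood fit on the counts, TMM factors and genes kept by filterByExpr, which left 15068 of 32883 genes. All 9 libraries entered one fit with a mean per group. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes are the fold change divided by the square root of F. Levels are TMM-scaled CPM, as mean ± SD of 3 libraries. A gene without a read in one group is given a lower bound on its fold, computed against 3 reads summed over that group. For 31 gene lists fixed before the data were examined (776 entries, of which 746 matched a row of the table), camera in limma 3.58.1 was run on log2 CPM (prior count 2) with its preset inter-gene correlation of 0.01 and adjustment over the lists. Alternatives were camera with an estimated correlation, and fry, whose test asks whether a list's genes move one way on balance, with a mixed version for change in either direction. Entries were matched by the symbols in the table, and 3 by synonym or Ensembl identifier from RefSeq's gene table for assembly GRCr8, used for names only.

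Genes were named by a rule fixed before the data were examined. Where fewer than 10 genes passed in AIA against NC or TZG against AIA, the rule took the 5 smallest p in each direction with a mean of at least 5 CPM in the higher group and a proper symbol. For TZG against NC it took the 3 highest and 3 lowest fold changes among passing genes with the same limits whose libraries did not overlap. For genes moved back it took the largest changes, of which there were none. Il1b, Il6, Tnf, Mmp3, Mmp13, Ccl2, Prg4 and Acp5 were taken in every comparison, and from each list the 2 smallest p past the threshold in the first 2 comparisons, which gave none. All other examples from the lists were chosen after their values were seen, as members with small p. Of the genes taken by the rule 1 is not reported here, nor is 1 of the examples.

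Alternatives chosen before the data were examined were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, no filter on low counts, a stricter filter, a fit of 2 groups at a time, an absolute log2 fold change of at least 1, an adjusted p under 0.01, the skeletal muscle list as a covariate, limma on log2(FPKM + 1), and each library left out in turn. Other pseudocounts and other filters on FPKM were listed only for a table without counts and were not run. Chosen after seeing the data were a fit without C61, M8 and G48, a fit with the 5 columns matched by number, and a wider gene choice for the position of TZG.

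The gene test was tested on simulated data drawn from the real means, library sizes and fitted dispersions, with 200 genes changed among those tested. For AIA against NC it recovered 26% of 2-fold, 70% of 4-fold, 78% of 8-fold and 90% of 16-fold changes, with 3 false calls. For TZG against AIA the shares were 30%, 74%, 78% and 90%, with 4 false calls, and for TZG against NC 24%, 78%, 94% and 94%, with 7 false calls. These runs had 14925, 14948 and 14935 genes in the same order. Simulated genes vary independently, and the draws differ from the real counts: when AIA and NC were drawn at their observed means, which takes the noise of 3-library means for true differences, with TZG equal to AIA, an average of 602.1 genes passed in the same direction in both AIA against NC and TZG against NC, where 2 did in the real counts. Whether these shares hold for the real libraries was not tested. For the lists, 5 of 5 shifted lists were called in each simulated comparison and none of the 22, 26 and 22 lists that share no shifted member.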

Results

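Gene expression was measured by RNA sequencing in synovium of Lewis rats, in 3 libraries of each of the groups NC, AIA and TZG, read here as control, arthritis model and extract group. The series title and design text name rheumatoid arthritis and an intervention with a liquid extract. Totals were 15800852, 15378480 and 12536231 reads in NC (C56, C59, C61), 13471552, 14295934 and 14335920 reads in AIA (M2, M6, M8) and 14275020, 13765527 and 16402126 reads in TZG (G30, G31, G48). The first principal component held 49% of the variance of log2 CPM and the next 15.4%. Of the 9 libraries, 4 were placed in AIA or TZG by the letter of their column, which is also how the authors averaged them. Which sample each of these is remains unknown.

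The dissected tissue differed between libraries. Transcripts of skeletal muscle were abundant in NC library C61, where actin Acta1 stood at 8190 CPM, against 455 in C59, 18 in C56 and at most 11.6 in the AIA and TZG libraries. Mitochondrial transcripts took 14.1% of the reads of C61 and 5.7% to 8.4% of those of the other libraries. Cartilage collagen Col2a1 reached 5410 CPM in G48, 358 in G30 and 91.7 in M8, against at most 7.33 elsewhere, and the bone gene Ibsp 673, 44.5 and 13 CPM in the same libraries. Slc4a1, the anion exchanger of red cells, stood at 343 CPM in M8 and at 26.1 to 39.3 in the other AIA and TZG libraries. The adipocyte gene Adipoq was lowest in G48, at 258 CPM, and lay between 697 and 2450 CPM in the others.

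**Figure D1:**
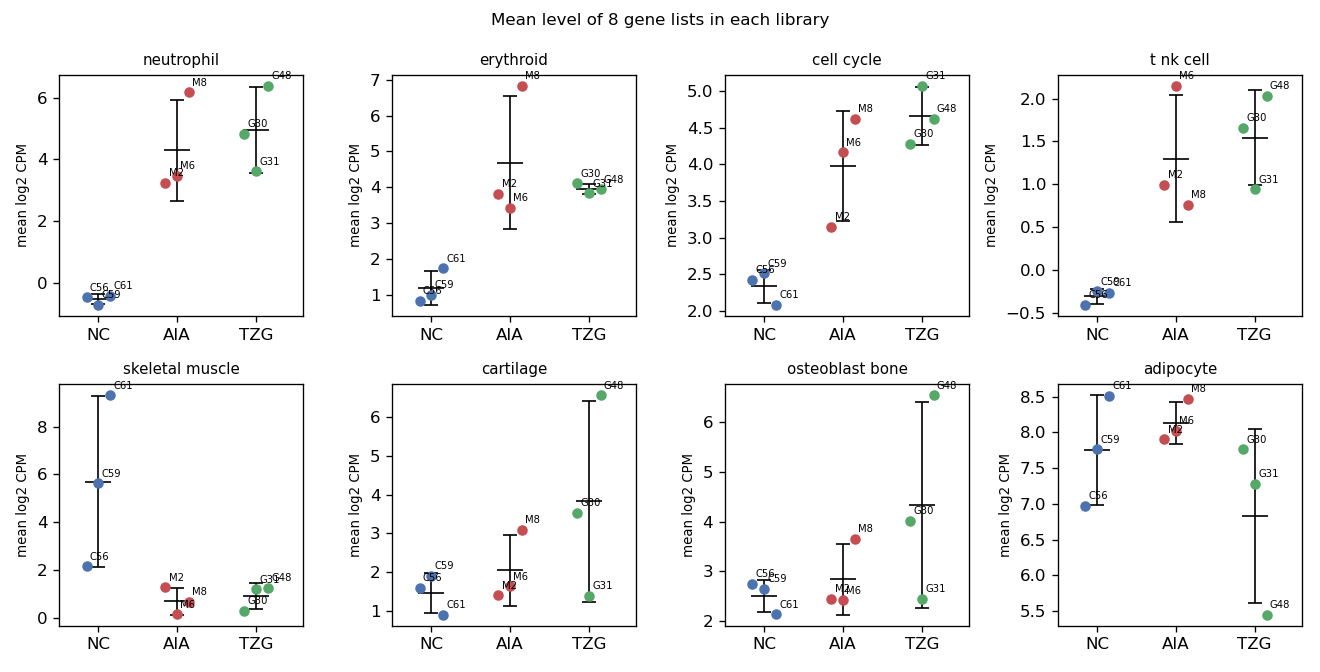
Mean log2 CPM of the members of 8 gene lists in each library, by group; points are libraries, and lines give the mean and SD of 3 libraries. The neutrophil, erythroid, cell cycle and T and NK cell lists are higher in every AIA and TZG library than in NC, skeletal muscle varies most within NC, and cartilage and bone are highest in G48.

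The comparison of AIA with NC asks what the arthritis model changed. Plac8, a gene of myeloid and other immune cells, rose from 18.9 ± 1.71 to 67.7 ± 16.3 CPM (log2 fold change 1.84 ± 0.19 SE, edgeR adjusted p = 0.04). Nr1d1, which encodes the clock repressor REV-ERB alpha, fell from 173 ± 26.2 to 53.4 ± 7.18 CPM (log2 fold change -1.69 ± 0.15 SE, adjusted p = 0.031). In the deposited table Plac8 (ENSRNOG00000002217) lies on chromosome 14 at 10692764 to 10714524 and Nr1d1 (ENSRNOG00000009329) on chromosome 10 at 86683875 to 86690815, with no build given in the sources used here. The genes next in rank did not pass. Properdin (Cfp) stood at 35.2 ± 9.54 against 8.91 ± 1.03 CPM (adjusted p = 0.058), the ubiquitin-like Ubd at 9.89 ± 5.37 against 0.247 ± 0.0918 CPM (adjusted p = 0.058) and metallothionein Mt1 at 31.1 ± 8.25 against 7.04 ± 1.18 CPM (adjusted p = 0.075). On the lower side Col4a5, Fhl1, Cuedc1 and Cobl had log2 fold changes of -1.22, -0.98, -0.71 and -1.5, with adjusted p from 0.075 to 0.078. The libraries of both groups did not overlap for any of these genes. Chance gives this for 10% of unselected genes, but these were picked for small p, so it adds no support.

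Inflammatory genes fixed in advance did not pass over all genes in AIA against NC. Il1b, a central cytokine of joint inflammation, stood at 9.11 ± 2.94 CPM in AIA and 1.23 ± 0.459 in NC (log2 fold change 2.9 ± 0.4 SE, adjusted p = 0.075). Ccl2, Mmp3 and Mmp13 had log2 fold changes of 1.57, 2.69 and 4.54 with adjusted p of 0.18, 0.26 and 0.34, and Tnf and Acp5 of 1.28 and 0.79 with adjusted p of 0.25 and 0.72. Il6 rested on 33 reads in AIA and 21 in NC (log2 fold change 0.69, adjusted p = 0.82; -0.01 without M6). For the joint lubricant Prg4 the value was -0.21 (adjusted p = 0.92), with the sign turning without C56, C59 or M6, at 0.14, 0.03 and 0.03.

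Of the 31 lists, 19 moved in AIA against NC by camera with its preset correlation, 14 up and 5 down, and none did with an estimated correlation. The neutrophil list had the largest rise: all 21 members were higher, with a median log2 fold change of 6.54 when the 7 members without a read in one group are set at their bound (7.58 as fitted; camera adjusted p = 8.3e-22, adjusted p = 0.23 with an estimated correlation). Over all genes 0 of its members passed and adjusted over the list alone 18 did. S100a9, a subunit of the neutrophil protein calprotectin, stood at 386 ± 478 CPM against 2.04 ± 0.974, and the growth factor receptor Csf3r at 40.1 ± 28.5 against 1.75 ± 0.438 CPM. The list stood at 6.18 mean log2 CPM in M8 and 3.24 and 3.46 in M2 and M6, and marrow precursor genes other than Mpo summed to 139 CPM in M8 and 9.95 and 7.62 in M2 and M6, so marrow in the tissue is not excluded as a source. All 29 cell cycle genes were higher, with a median of 1.84 (camera adjusted p = 2.3e-21, adjusted p = 0.23 with an estimated correlation) and 24 past the threshold adjusted over the list alone, among them Top2a at 43.2 ± 25.3 against 6.75 ± 1.88 CPM. T and NK cell genes had a median of 2.11 with 28 of 30 higher and 16 past the threshold adjusted over the list alone (camera adjusted p = 7.2e-13, adjusted p = 0.23 with an estimated correlation). Cd8a, the coreceptor of cytotoxic T cells, stood at 6.13 ± 3.27 against 0.617 ± 0.173 CPM. B and plasma cell genes had a median of 2.03 and 11 of 21 past the threshold adjusted over the list alone (camera adjusted p = 3.6e-08, adjusted p = 0.23 with an estimated correlation). The erythroid list had a median of 4.66 with all 15 members past the threshold adjusted over the list alone (camera adjusted p = 1.3e-13, adjusted p = 0.23 with an estimated correlation), and its mean level was highest in M8. With one library left out the erythroid median fell to 2.73, the B and plasma cell median to 1.28 and the T and NK cell median to 1.32, and without C61, M8 and G48 the erythroid median was 2.4.

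The IL-17 response, antigen presentation, NF-kB and inflammasome, chemokine, complement, JAK-STAT, macrophage and matrix protease lists also moved up, with medians of 1.26, 0.75, 0.36, 1.18, 0.45, 0.35, 0.43 and 0.26. Their adjusted p with an estimated correlation were 0.16, 0.23, 0.31, 0.23, 0.31, 0.25, 0.6 and 0.36 in the same order. Of the 16 IL-17 response genes 11 stand in other lists as well. Members higher past the threshold adjusted over the list alone numbered 7 of 16, 3 of 21, 8 of 31, 4 of 26, 4 of 22, 0 of 20, 1 of 20 and 1 of 31, and 1 NF-kB member was lower. Complement C3 stood at 265 ± 98.6 against 11.5 ± 1.09 CPM and the inflammasome sensor Nlrp3 at 14.5 ± 2.51 against 5.13 ± 1.81 CPM. Complement, macrophage and matrix proteases lost the call without C61. Medians ran from 0.17 to 0.74, 0.05 to 0.75 and 0.15 to 0.41 in these 3 lists with one library left out, and from 0.17 to 0.56 for NF-kB. The adipocyte list had a median of 0.16 (camera adjusted p = 0.047, adjusted p = 0.81 with an estimated correlation) and lost the call without C56, C59, M8 or G31; its median ran from -0.1 to 0.67. The 5 lists that moved down were skeletal muscle, Schwann cell and nerve, immediate early, tendon and endothelium, with medians of -7.63, -0.43, -0.55, -0.88 and -0.21 and adjusted p of 0.25, 0.23, 0.31, 0.58 and 0.7 with an estimated correlation. Adjusted over the list alone, 19 of 21 muscle and 2 of 25 endothelial genes were lower and 0 in the other 3 lists. Skeletal muscle was highest in C61. With one library left out the muscle median ran from -8.64 to -4.21, the immediate early from -0.68 to -0.35 and the endothelial from -0.39 to -0.02. The tendon call was lost without C56, C59, M2 or M8 and the endothelium call without C56, C61, M6, M8, G31 or G48. Without C61, M8 and G48 the macrophage list did not pass (adjusted p = 0.11) and endothelium had a median of 0.04. The cartilage, bone, osteoclast, cytokine, fibrosis, hypoxia, interferon, keratinocyte, mast cell, oxidative phosphorylation, PI3K and synovial fibroblast lists did not move in this comparison, with medians between -0.39 and 0.49; for hypoxia and interferon the mean, at -0.08 and 0.16, had the other sign than the median, and for mast cells the mean and the test did. Adjusted over the list alone, 2 cytokines and 3 osteoclast genes were higher. Some of these lists gained a call in other fits. Without C61, M8 and G48 the synovial fibroblast, interferon and fibrosis lists passed downward, with medians of -0.53, -0.4 and -0.25 and adjusted p of 6.1e-05, 0.0026 and 0.046, and oxidative phosphorylation passed upward, with a median of 0.16 and an adjusted p of 0.0043. With single libraries left out, oxidative phosphorylation passed downward without C56, C59 or M8 and upward without C61, synovial fibroblast downward without C61 or M2, and fibrosis downward without C61. Cytokines passed upward without C56 or M8, mast cells without C59 and osteoclasts without M2.

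Counts of genes past the threshold in AIA against NC were small and moved with the tool. The edgeR test gave 1 higher and 1 lower gene of 15068, with 2264 at an unadjusted p under 0.05 where 753 would be expected by chance and 183 at an adjusted p under 0.1. DESeq2 gave 571 higher and 352 lower, limma-voom 0 and 1, and the authors' deposited table lists 557 higher and 296 lower genes at a q-value under 0.05. Without M2 the edgeR counts were 90 and 8, without M8 13 and 1, without G48 5 and 1, and without C61, M8 and G48, chosen after seeing the data, 94 and 86. Neither Plac8 nor Nr1d1 passed without C56, C59, M6, G30 or G31, where the counts were 0 and 0, or in a fit of 2 groups, where another gene did, and Plac8 did not pass without C61, where the counts were 1 and 4.

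**Figure D2:**
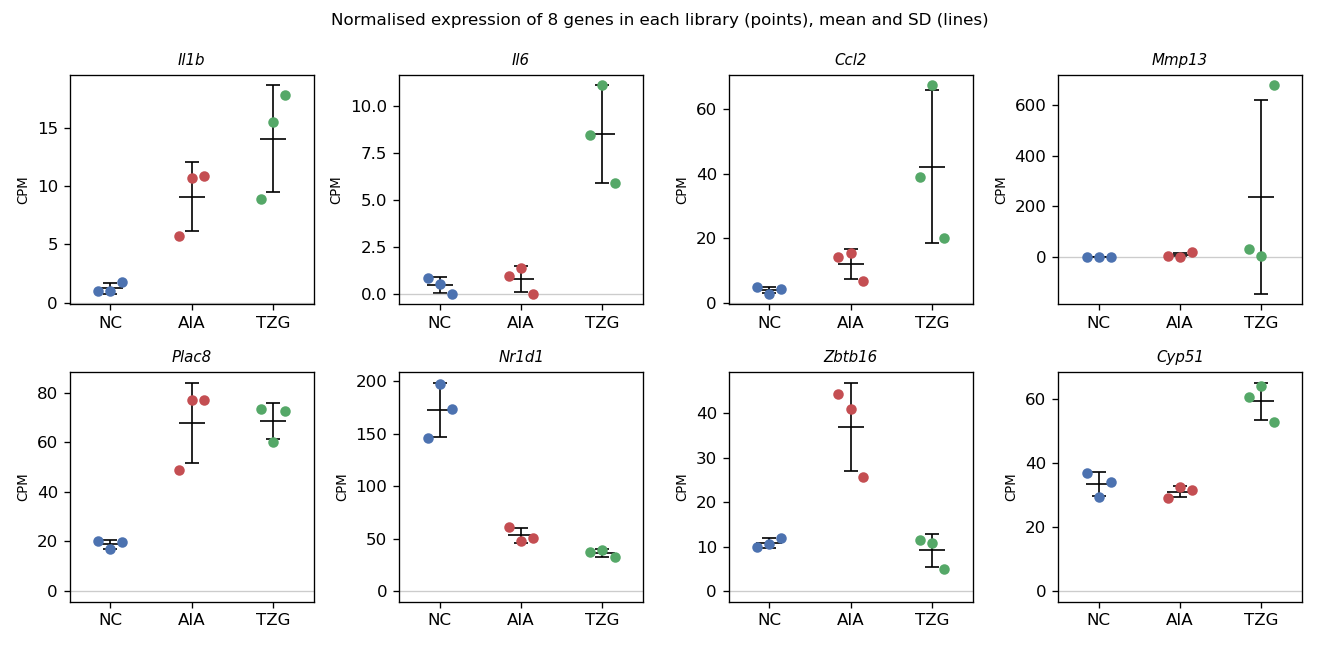
Normalised expression in CPM of 8 genes in the 3 libraries of each group; points are libraries, and lines give the mean and SD. Il1b and Plac8 are higher in every AIA and TZG library than in NC, Nr1d1 is lower, Zbtb16 is highest in AIA, and Cyp51 and Il6 are highest in TZG.

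The comparison of TZG with AIA asks what differed in the extract group from the arthritis model. No gene passed in edgeR: of 15068 genes 1894 had an unadjusted p under 0.05 (753 expected by chance), and the smallest adjusted p was 0.26. Among the higher genes with the smallest p were Cyp51, which serves cholesterol synthesis, Tdg, Atp10a and Trib1. Cyp51 stood at 59.2 ± 5.76 CPM in TZG and 31 ± 1.7 in AIA (log2 fold change 0.93 ± 0.12 SE). Tdg, Atp10a and Trib1 had log2 fold changes of 0.6, 0.84 and 0.86. Among lower genes the 5 smallest p belonged to Akap12, Dgkb, Zbtb16, Utrn and Pdzd2, with log2 fold changes of -1.01, -0.99, -2.01, -0.89 and -0.78. Zbtb16, which encodes a transcription factor, stood at 9.15 ± 3.62 CPM in TZG and 36.9 ± 9.87 in AIA, and in the 3 NC libraries at 9.9, 10.5 and 12. Each of these 9 genes had an adjusted p of 0.26 and libraries of TZG and AIA that did not overlap. Il6 stood at 8.49 ± 2.63 CPM in TZG and 0.77 ± 0.697 in AIA (log2 fold change 3.45 ± 0.98 SE, adjusted p = 0.3), and Ccl2 at 42.1 ± 23.7 against 12.1 ± 4.72 CPM (log2 fold change 1.8 ± 0.46 SE, adjusted p = 0.27). Mmp13, Acp5, Mmp3, Il1b, Tnf and Prg4 had log2 fold changes of 4.65, 2.15, 0.91, 0.63, -0.23 and -0.85, with adjusted p from 0.33 to 0.85. Without G48 the values for Mmp13, Acp5 and Mmp3 were 1, 0.34 and -0.1, and for Tnf the value was 0.17 without M6.

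Of the 31 lists, 14 moved in TZG against AIA by camera with the preset correlation, 11 up and 3 down, and none with an estimated correlation. All 28 adipocyte genes were lower, with a median log2 fold change of -1.01 (camera adjusted p = 1.9e-09, adjusted p = 0.73 with an estimated correlation), and the list stood lowest in G48; the median ran from -1.42 to -0.59 with one library left out and was -0.41 without C61, M8 and G48. All 29 cell cycle genes were higher, with a median of 0.64 (camera adjusted p = 1.1e-07, adjusted p = 0.73 with an estimated correlation) that ran from 0.32 to 0.97 with one library left out. Genes of fibrous matrix had a median of 0.71 with 24 of 29 higher (camera adjusted p = 2.5e-05, adjusted p = 0.73 with an estimated correlation). This median ran from 0.48 to 1.03 with one library left out and was 0.29 without C61, M8 and G48 (camera adjusted p = 0.0077). Adjusted over the list alone 2 passed, the crosslinking enzyme Lox at 513 ± 47.4 against 139 ± 89.2 CPM and Col12a1 at 555 ± 471 against 78.3 ± 51.8 CPM. Immediate early, cytokine, IL-17 response, NF-kB and hypoxia lists moved up with medians of 0.41, 0.41, 0.57, 0.15 and 0.25, and adjusted p of 0.73, 0.73, 0.73, 0.75 and 0.73 with an estimated correlation. With one library left out the first 4 medians ran from 0.19 to 0.66, 0.38 to 0.77, 0.06 to 1.02 and 0.07 to 0.26. Nfkbiz, an inducible regulator of NF-kB target genes, stood at 36.4 ± 5.97 against 15.3 ± 4.83 CPM. Cartilage, bone, osteoclast and matrix protease lists had medians of 3.64, 2.03, 0.95 and 0.57 and adjusted p of 0.75, 0.75, 0.75 and 0.73 with an estimated correlation. Adjusted over the list alone, 3 IL-17 response, 2 immediate early, 2 NF-kB and 2 matrix protease genes were higher and 1 endothelial gene lower, and 0 passed in the other lists that moved apart from fibrous matrix. The cartilage, bone, osteoclast and matrix protease calls were lost without G48, the library richest in cartilage and bone transcripts, and their medians fell to 0.34, 0.31, 0.08 and 0.04 there. Endothelium and interferon response moved down with medians of -0.21 and -0.19 (adjusted p of 0.78 and 0.84 with an estimated correlation), and the interferon call was lost without M8 or G48 and turned without C61, M8 and G48, to a median of 0.31. With one library left out these 2 medians ran from -0.31 to -0.02 and -0.42 to 0.06. The hypoxia call was lost without C59, M2, M6, M8, G30 or G31, the NF-kB call without M2, M8 or G48, the immediate early call without M6, and the endothelium call without M2, G30 or G48. The neutrophil, erythroid, T and NK cell, B and plasma cell, macrophage, antigen presentation, chemokine and complement lists did not pass, with medians of 0.4, -1.68, 0.22, 0.05, 0.24, -0.06, 0.09 and -0.01. Nor did the keratinocyte, mast cell, JAK-STAT, oxidative phosphorylation, PI3K, Schwann cell, skeletal muscle, synovial fibroblast and tendon lists. Adjusted over the list alone, 4 chemokines were higher and 1 lower, 2 JAK-STAT genes were higher and 3 lower, and 1 B and plasma cell gene was higher and 1 lower. Several of these medians turned with single libraries: with one library left out, the neutrophil median ran from -0.78 to 2.34, the erythroid from -2.19 to 0.29, the T and NK cell from -0.32 to 0.95 and the B and plasma cell from -0.49 to 0.65. The neutrophil list passed upward without M8 or G31, and the erythroid list downward without M2 or M6. T and NK cell genes passed upward without M6 or G31, chemokines without M6 and tendon without G31, while the Schwann cell list passed downward without M6 or G30 and oxidative phosphorylation without C61 or G31. Without C61, M8 and G48 the neutrophil and erythroid lists passed upward, with medians of 0.8 and 0.35 and adjusted p of 0.00033 and 0.041, and complement passed downward, with a median of -0.41 and an adjusted p of 0.038. The cartilage, bone, matrix protease and NF-kB calls were lost in that fit, with adjusted p of 0.47, 0.37, 0.71 and 0.14.

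DESeq2 called 137 genes higher and 136 lower in TZG than in AIA and limma-voom 0 and 0. The authors' deposited table lists 81 higher and 34 lower genes at a q-value under 0.05.

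**Figure D3:**
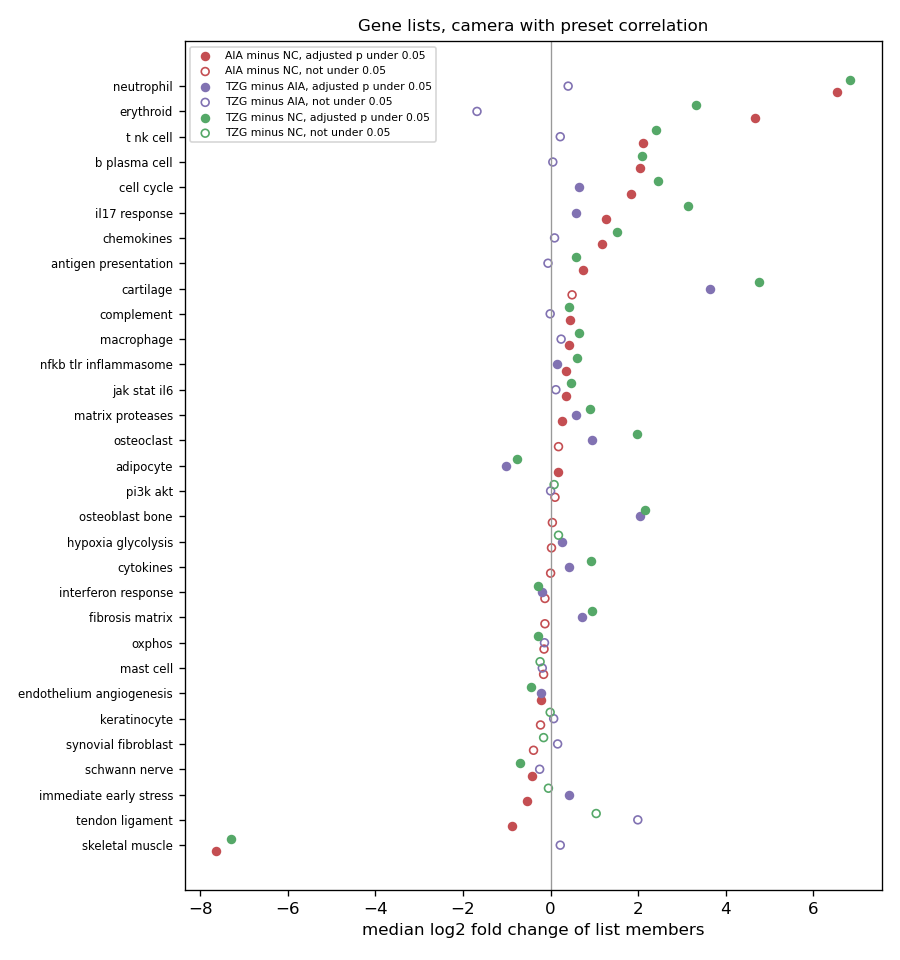
Median log2 fold change of the members of each of the 31 gene lists in the 3 comparisons, with members without a read in one group set at their bound. Filled points have a camera adjusted p under 0.05 with the preset correlation; no list passes with an estimated correlation. The neutrophil list lies highest in both comparisons with NC, at 6.54 and 6.84, and skeletal muscle lowest, at -7.63 and -7.3.

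The extract group was also compared with the control. In edgeR 873 genes were higher and 682 lower in TZG than in NC. The highest were the defensins Np4, Defa5 and RatNP-3b, genes of antimicrobial peptides, whose near-identical copies make the assignment of reads uncertain. Np4 had 0 reads in NC and 225 ± 226 CPM in TZG, at least 3166-fold higher (adjusted p = 0.035), and Defa5 was at least 2509-fold higher (adjusted p = 0.035). G48 carries much of both limits, which are 1434-fold and 1140-fold without it. RatNP-3b stood at 179 ± 177 against 0.106 ± 0.183 CPM (adjusted p = 0.02). The lowest were the muscle genes Mb, Pvalb and Tnnc2, with log2 fold changes of -9.58, -9.02 and -8.97 and adjusted p of 0.032, 0.027 and 0.039; muscle transcripts were highest in C61. Il1b rose from 1.23 ± 0.459 to 14.1 ± 4.59 CPM (log2 fold change 3.52 ± 0.41 SE, adjusted p = 0.012) and Ccl2 from 4.08 ± 1.02 to 42.1 ± 23.7 CPM (log2 fold change 3.37 ± 0.5 SE, adjusted p = 0.014). Il6 rose as well (log2 fold change 4.14 ± 1.03 SE, adjusted p = 0.041), as did the collagenase Mmp13 (9.19 ± 2.17 SE, adjusted p = 0.034), for which G48 held 676 CPM and G30 and G31 34 and 3.46 CPM. Mmp3, Acp5, Tnf and Prg4 did not pass, with log2 fold changes of 3.6, 2.94, 1.04 and -1.06 and adjusted p of 0.064, 0.066, 0.19 and 0.33. Il1b and Ccl2 passed with each library left out in turn. Of the other genes past the threshold, Il6 lost the call without any library but M8 and Mmp13 without C56, C59, C61, M2, M6 or G30. Np4 and Defa5 lost it without any NC or TZG library, and RatNP-3b without any NC library. Mb lost it without M2, M6, G30, G31 or G48, Pvalb without G30, G31 or G48, and Tnnc2 without any library but C56, while Acp5 gained it without G31. Without G48 the log2 fold changes of Mmp13, Acp5 and Mmp3 were 5.54, 1.13 and 2.59, and without C61 those of Mb, Pvalb and Tnnc2 were -6.78, -5.2 and -4.97.

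By list, 24 of 31 moved in TZG against NC, 18 up and 6 down, and none with an estimated correlation, for which the smallest adjusted p was 0.14. Below, list members that rose or fell are only those past the threshold over all genes. All 29 cell cycle genes were higher and 28 passed, with a median of 2.46 (camera adjusted p = 1.4e-20, adjusted p = 0.36 with an estimated correlation). Top2a stood at 73.2 ± 17.7 against 6.75 ± 1.88 CPM. All 21 neutrophil genes were higher and 13 passed, with a median of 6.84 at the bounds (camera adjusted p = 1.6e-15, adjusted p = 0.36 with an estimated correlation). Marrow precursor genes other than Mpo summed to 131, 11.8 and 150 CPM in G30, G31 and G48, so marrow is not excluded as a source here either. In TZG 9 of 16 IL-17 response genes, 9 of 30 T and NK cell genes, 9 of 31 NF-kB genes, 10 of 31 matrix protease genes, 6 of 26 chemokines and 4 of 17 cytokines rose, and 1 matrix protease, 1 NF-kB gene and 3 chemokines fell. Whether past the threshold or not, 15, 28, 24, 24, 21 and 12 members were higher in the same order. Adjusted p with an estimated correlation were 0.14 for IL-17 response and 0.36 for the other 5. Adjusted over the list alone, 29 cell cycle and 19 neutrophil genes were higher, and in the 6 lists just named 13, 18, 12, 14, 9 and 5. Cd8a rose to 19.2 ± 6.03 from 0.617 ± 0.173 CPM (adjusted p = 0.011) and Timp1, an inhibitor of matrix proteases, to 223 ± 46.1 from 43.7 ± 14.5 CPM (adjusted p = 0.015). The B and plasma cell, antigen presentation, complement, macrophage, JAK-STAT, erythroid, osteoclast, fibrosis, cartilage and bone lists moved up too, with 4, 2, 3, 3, 4, 2, 3, 3, 1 and 1 members that rose (12, 3, 4, 4, 8, 9, 5, 5, 13 and 1 adjusted over the list alone), 1 JAK-STAT and 1 fibrosis gene that fell, and adjusted p between 0.36 and 0.6 with an estimated correlation. Of these, cartilage and bone lost the call without G48 and without C61, JAK-STAT without C61 or G30, and complement, macrophage and fibrosis without C61. With one library left out the medians of cartilage, bone, osteoclast, fibrosis and matrix protease lists ran from 1.2 to 5.39, 0.3 to 3.11, 0.49 to 2.42, 0.36 to 1.09 and 0.37 to 1.1, lowest without G48 in each. The complement and macrophage medians ran from 0.24 to 0.7 and 0.21 to 1.1. Of 21 muscle genes 16 fell (adjusted p = 0.43 with an estimated correlation), as did 3 of 18 Schwann cell genes, among them periaxin Prx at 23.5 ± 2.77 against 49.4 ± 8.21 CPM (adjusted p = 0.014), and 5 of 25 endothelial genes (1 rose), among them the sialomucin Emcn at 65.8 ± 2.8 against 146 ± 31.2 CPM (adjusted p = 0.013); their lists had adjusted p of 0.36 and 0.52 with an estimated correlation. Adjusted over the list alone, 19 muscle, 7 Schwann cell and 7 endothelial genes were lower. The muscle median ran from -7.97 to -4.1 and the endothelial from -0.61 to -0.26 with one library left out. Adipocyte, interferon and oxidative phosphorylation lists moved down (adjusted p of 0.64, 0.67 and 0.75 with an estimated correlation). Of their members 25 of 28, 23 of 30 and 29 of 30 were lower, none past the threshold over all genes. Each list lost the call without G48, the adipocyte and oxidative phosphorylation lists also without C61, and the interferon list without C56 or C59. The adipocyte and interferon medians ran from -1.15 to -0.28 and -0.51 to -0.05. Oxidative phosphorylation turned without C61, to a median of 0.1, and without C61, M8 and G48 it passed upward, with a median of 0.19 and an adjusted p of 0.002, where the adipocyte list had a median of 0.11 and an adjusted p of 0.23. The tendon, synovial fibroblast, mast cell, keratinocyte, hypoxia, immediate early and PI3K lists did not pass; the tendon list had a median of 1.04 but a downward test. Among their members 4 hypoxia, 2 PI3K, 1 immediate early and 1 synovial fibroblast gene rose, and 3 synovial fibroblast genes and 1 each of hypoxia, mast cell and tendon genes fell. Without C61, M8 and G48 the synovial fibroblast and tendon lists passed downward, with medians of -0.85 and -1.09 and adjusted p of 0.0016 and 0.015, and hypoxia passed upward, with a median of 0.48 and an adjusted p of 0.0016. Leaving out C61 alone gave the synovial fibroblast and hypoxia calls as well. In the fit without C61, M8 and G48 the complement, macrophage, osteoclast, fibrosis, cartilage, bone and interferon calls were lost, with adjusted p of 0.5, 0.13, 0.071, 0.72, 0.72, 0.72 and 0.5.

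With the muscle list as a covariate the TZG against NC counts fell to 0 and 1, and at an adjusted p under 0.01 to 1 and 1. The 5 columns matched by number leave G30 alone in TZG, so no counts are given for that fit. DESeq2 gave counts of 1616 and 1273, and a fit of 2 groups 526 and 237. Without C56 they were 150 and 185, without C59 406 and 451, without C61 570 and 613, without G30 376 and 211 and without G31 317 and 143. The lower count alone moved as far without M2, M6 and G48, to 446, 406 and 384. Without C61, M8 and G48 the counts were 1155 and 1001, of which 1125 genes were among the 1555 of the full fit; the authors' deposited table lists 1106 and 591 genes at a q-value under 0.05.

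The last question was whether genes changed in AIA moved back in TZG. With 2 genes past the threshold in AIA against NC and 0 in TZG against AIA, no gene did so in edgeR, and none moved further; simulations with TZG equal to AIA gave 0.05 on average, and independent lists of these sizes give 0. DESeq2 gave 20, of which 17 were higher in AIA and lower in TZG and 3 the reverse, against 5.67 and 3.52 for independent lists; 13 moved further, 8 upward and 5 downward, against 5.71 and 3.5. The AIA libraries enter both comparisons with opposite sign, which by itself favours moves back over moves further. Because no unchanged groups were simulated for DESeq2, whether the 20 exceed that effect cannot be told, and no reversal is concluded from them. Among the 20 were Zbtb16, the lipase gene Pnpla2 and the mesothelial gene Msln, with log2 fold changes of 1.77, 2.06 and -1.89 in AIA against NC and of -2, -2.02 and 2.6 in TZG against AIA; these 3 were chosen after their values were seen. On a scale where 0 is AIA and 1 is NC, the median position of TZG over Plac8 and Nr1d1 was -0.17, on the far side of AIA from NC. Nr1d1 carried this value, with a log2 fold change of -0.56 in TZG against AIA. Plac8 overlapped, at 60.2 to 73.3 CPM in TZG and 49 to 77.1 in AIA. Over the 865 genes with an unadjusted p under 0.01, a choice made after seeing the data, the position was -0.11, with -0.1, -0.09 and -0.24 in G30, G31 and G48. Refits changed the genes as well as the libraries: over the 98, 14 and 6 genes that passed without M2, M8 and G48 it was -0.07, -0.06 and -0.05. When genes were chosen without one AIA library and the position measured with it, the medians were -0.78, -0.17 and -0.05 for M2, M6 and M8.

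Log2 fold changes of AIA against NC and TZG against NC correlated across genes at 0.849, with a covariance of 0.578; unchanged groups sharing the NC libraries gave 0.502 and 0.081 in simulation, and TZG drawn equal to AIA gave 0.902 and 0.689. Both genes past the threshold in AIA against NC passed in the same direction in TZG against NC, where independent lists give 0.06 and 0.05 and simulated unchanged groups 0. The simulated unchanged groups already share the NC libraries, which gave a covariance of 0.081 against the 0.578 observed. The simulated draws differ from the real counts, and with 3 NC libraries no split of the controls leaves 2 in each part. How much the shared controls add in the real libraries is therefore not known. For AIA against NC and TZG against AIA the correlation was 0.104 and the covariance 0.038, against -0.217 and -0.074 in simulations with TZG equal to AIA and -0.501 and -0.081 with no group changed.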

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

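The fits without C61, M8 and G48 together, with the 5 columns matched by number, and with genes at an unadjusted p under 0.01 were chosen after the data were seen; the others were planned. No paired analysis was possible because the labels give no replicate numbers shared between groups. RLE and upper-quartile factors and the stricter filter moved no count of genes by over 1.5 times, and the causes of the changes listed here were not tested unless stated.

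For AIA against NC, higher and lower counts of 1 and 1 became 571 and 352 with DESeq2, and 94 and 86 without C61, M8 and G48. They were 0 and 0 at an adjusted p under 0.01 and with the muscle covariate, which overlaps with the NC group. With the 5 columns matched by number M6 stands alone in AIA and G30 alone in TZG, which leaves little to estimate the spread, so no counts are given for that fit. The higher count was 0 with limma-voom, 3 without a filter and 4 with limma on FPKM, and the lower count 0 in a fit of 2 groups, whose 1 higher gene was neither of the 2. Leaving out one library gave 0 to 90 higher and 0 to 8 lower genes: the pairs were 90 and 8 without M2, 13 and 1 without M8, 5 and 1 without G48, 1 and 4 without C61, and 0 and 0 without C56, C59, M6, G30 or G31.

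For TZG against AIA, counts of 0 and 0 became 137 and 136 with DESeq2, and the lower count 1 without C61, M8 and G48; leaving out any one library gave 0 and 0. For TZG against NC, 873 and 682 became 1616 and 1273 with DESeq2, 526 and 237 in a fit of 2 groups, 1 and 1 at an adjusted p under 0.01, and 0 and 1 with the muscle covariate. The lower count was 317 at an absolute log2 fold change of at least 1 and 377 with limma on FPKM, while the higher counts there were 585 and 820. Leaving out one library gave 150 to 821 higher and 143 to 613 lower genes: 150 and 185 without C56, 406 and 451 without C59, 570 and 613 without C61, 376 and 211 without G30, 317 and 143 without G31, 587 and 384 without G48, 681 and 446 without M2, 593 and 406 without M6, and 821 and 493 without M8.

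Genes moved back numbered 20 with DESeq2 and 1 without C61, M8 and G48, against 0. The position of TZG was -0.33 with limma-voom, over 1 gene, and -0.25 to -0.05 with one library left out; no value could be had where no gene passed in AIA against NC. Lists moved numbered 19, 14 and 24 in AIA against NC, TZG against AIA and TZG against NC; they were 0, 0 and 0 with an estimated correlation, 9, 0 and 11 with fry, and 17 to 20, 7 to 17 and 18 to 24 with one library left out, the 7 being without G48. The mixed version of fry gave 18, 4 and 23.

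Of 634 recomputed fold changes of named genes, 522 kept their direction and side of the threshold, 64 lost the threshold, 41 gained it and 7 turned. With one library left out Il6 ran from -0.01 to 1.4 and Prg4 from -0.71 to 0.14 in AIA against NC, and Tnf from -0.48 to 0.17 and Mmp3 from -0.1 to 1.29 in TZG against AIA. In AIA against NC those that turned were Il6 at -0.01 without M6, and Prg4 at 0.14 without C56, 0.03 without C59 and 0.03 without M6. In TZG against AIA they were Tnf at 0.17 without M6, and Mmp3 at -0.1 without G48 and -0.57 without C61, M8 and G48. Depth limits the low genes most: Il6 and Tnf rested on 19 to 47 reads per group in AIA and NC.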

Other observations

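The counts of sample splits were chosen before their results were seen; all other tests here, and the clock, sterol and marrow gene lists, were chosen after the patterns had been seen. The tests for G48, marrow, muscle and sterol genes were changed after a first result was known; a first version for marrow argued against it and a first, looser bound for G48 argued against that.

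Genes of the daily clock stood lower in AIA and TZG than in NC. In all, 8 genes in the phase of Nr1d1 were lower in AIA than in NC, with a median log2 fold change of -0.91, and lower in TZG than in NC, with a median of -1.02; 1 and 5 of them passed in edgeR. Dbp, an output gene of the clock, had a log2 fold change of -1.57 in AIA against NC (adjusted p = 0.094) and fell by 1.84 on the log2 scale in TZG against NC (adjusted p = 0.015). The levels of most clock genes, both phases included, had been seen when the lists were written, and Per1, Per2 and Cry2 were left out of both; their log2 fold changes were -0.29, -0.37 and -0.39 in AIA against NC and 0.16, -0.25 and -0.66 in TZG against NC, where Cry2 passed (adjusted p = 0.015). The mean level of the 8 genes was 4.96 to 5.74 log2 CPM in NC and 4 to 4.4 in the other 6 libraries.

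Cholesterol synthesis genes stood higher in TZG than in AIA, though none passed. Of 23 members 18 were higher, with a median log2 fold change of 0.37, among them Sqle at 1.07, Idi1 at 0.89 and Mvd at 0.86, each with an adjusted p of 0.26 in edgeR. In AIA against NC 7 of the 23 were higher, with a median of -0.1. The hypothesis that the pathway moves as a unit was tested on the 11 members whose levels had not been seen when the list was written: camera gave an unadjusted p of 0.00014 with the preset and 0.0072 with an estimated correlation, with 9 of 11 higher and a median of 0.36. An earlier version on 17 members, 6 of which turned out to have been seen, gave 0.0019 and 0.035, with 12 of 17 higher and a median of 0.19. The 6 were Dhcr7, Insig1, Sc5d, Hmgcs1, Fdft1 and Msmo1, at -0.75, -0.15, -0.05, 0.04, 0.19 and 0.52. Leaving them out thus lowered the p-value, and not every member of the pathway rose. A joint shift of most members remains a hypothesis from the same libraries. Sqle, Idi1 and Mvd were chosen after their values were seen.

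TZG libraries stood further from NC than AIA libraries did. Over 1516 genes chosen with AIA and TZG pooled, the median log2 distance from NC was 0.74, 1.18 and 1.12 in M2, M6 and M8 and 1.3, 1.36 and 1.48 in G30, G31 and G48, a difference in means of 0.36 (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 can give). M2 carries part of this: without it the difference was 0.22, and without M6, M8, G30 or G31 it was 0.37 to 0.45. Without G48 the difference was 0.31, about as large as with it, and G30 and G31 both lay above every AIA library. In these leave-outs the 1516 genes were kept, so the library left out, G48 or M2 included, still shared in choosing them. Cartilage and bone tissue in G48 still cannot be told apart from an effect of the group, because of the spread in AIA: the lower of G30 and G31, at 1.3, lies above the AIA mean of 1.01 but below that mean plus 2 SD, 1.5. Tissue in the other TZG libraries is open too. The cartilage list stood at 3.53 mean log2 CPM in G30 and 1.38 in G31, against 1.4 to 3.09 in AIA, and in G31 Col2a1 and Ibsp were low, at 1.04 and 0.554 CPM, but Acan and Spp1 were higher than in G30, at 82.6 against 64.5 and 228 against 134 CPM. The limit rests on M2 as well, since without M2 it was 1.24, below G30 and G31. A biological difference between the groups stays open.

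Neutrophil genes were higher in all AIA and TZG libraries than in NC. Whether blood of unchanged make-up left in the tissue is the source depends on the red-cell gene used. The lowest ratio of S100a9 to Hbb reads in AIA and TZG was 12.4 times the highest in NC, which goes against it. Slc4a1, however, rose about as much as S100a9 in AIA against NC, with log2 fold changes of 7.26 ± 1.18 SE and 7.58 ± 1.23 SE. In NC Slc4a1 rested on 36 reads. In TZG it stood at 30 to 39.3 CPM and S100a9 at 156 to 780 CPM. More blood in AIA is therefore not excluded. Bone marrow in the dissected tissue as the only source cannot be told apart from immigrating cells: 2 of the 6 libraries had marrow precursor transcripts at or below the highest NC library, but Mpo, at 38.8 to 108 CPM in NC, sets that count, and the ratio of mature to precursor reads ran from 1.46 to 4.43. Free of Mpo, S100a9 reads per Elane read ran from 7.44 in G30 to 48.9 in G31, a spread that marrow of one fixed make-up would not give, but the make-up of marrow in these libraries is not known. The other 4 precursor genes summed to at most 0.0633 CPM in NC, 7.62 to 11.8 in M2, M6 and G31, and 131 to 150 in G30, M8 and G48, the 3 libraries that also held the most cartilage and bone transcripts. Immigration of neutrophils with arthritis, or blood of unchanged or another make-up, stays open.

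For the lower clock genes, muscle in the NC libraries as the whole cause is argued against. If all clock reads of C61 came from muscle, muscle in C56 and C59, scaled by the median ratio of muscle genes to C61, would supply 1.11% and 6.77% of their excess over the AIA and TZG mean (3.29% and 11.2% by the upper quartile). With the muscle list as a covariate all 8 genes stayed lower in both comparisons but none passed. Their median went from -0.91 to -1.02 in AIA against NC and from -1.02 to -0.72 in TZG against NC. Nr1d1 went from -1.69 ± 0.15 to -1.5 ± 0.22 SE in AIA against NC and from -2.25 ± 0.16 to -2.06 ± 0.21 SE in TZG against NC, so its calls ended with a small change in fold, a wider error and a residual degree of freedom less, the covariate being tied to the NC group. A part played by muscle in C61 stays open. Collection at another clock time may account for the pattern, since 6 genes of the opposite phase, 5 of them seen beforehand, had a median log2 difference of 0.5, AIA and TZG minus NC, and all 6 were higher. Loss of Nr1d1 for any reason would raise the same genes, because REV-ERB alpha represses them, so an effect of inflammation stays open, and the labels give no collection times.

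For AIA against NC, 1 of the 10 splits of the 6 libraries gave as many genes as the real one, which gave 2, and the highest other split gave 0. For TZG against NC it was again 1 of 10, with 1555 genes in the real split and 0 in the highest other. For TZG against AIA all 10 splits gave as many as the real count of 0, and the highest other, which set M2, M6 and G31 against the rest, gave 3. In each case 10 splits are too few for a share under 0.05.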
